A study of Mus musculus with 6 samples.

How the data were processed

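Gene expression was measured in dissected mouse kidney epithelium on 6 Affymetrix arrays, 3 from mice labelled Fh1 knockout (cystic tissue) and 3 from wild-type littermates, 1 array per sample. Fh1 encodes fumarate hydratase, the tricarboxylic acid (TCA) cycle enzyme that turns fumarate into malate. RNA was column-purified and biotin-labelled, per the labels' protocols. The samples are numbered 1 to 3 in each group. Nothing in the labels states that each sample came from a separate animal, so p-values measure the spread between these samples only.

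The authors deposited 1 table of 45101 probe sets by 6 samples. The deposited values are RMA expression values on the log2 scale. RMA (robust multi-array average) is named in the submitters' processing notes, and the log2 scale was read from the values, which ran from 2.9 to 14.8. The RMA version, software and chip definition are not given in the sources used here. RMA corrects background, normalises between arrays and summarises the probes of a set. It reports no detection call, so dim genes cannot be separated from background, and log2 folds of dim genes are compressed. Array medians ran from 6.20 to 6.25. No value was missing, no pair of arrays was identical, and all 6 columns were used. For arrays no counting depth exists, and precision is limited by 3 samples per group.

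Probe sets were named through the platform annotation supplied for this work, which can be old. Exactly 1 gene was listed for 34945 probe sets, several for 932 and none for 9160, and 64 were controls. Of the probe sets with 1 gene, 34741 carried the current symbol of their Entrez identifier in the RefSeq gene table of GRCm38.p6, and 204 had an identifier outside it and kept the annotation's symbol. No coordinates are given because the build behind the array is not stated. Each of the 18193 genes was represented by the probe set with the highest mean over the 6 arrays. Of these genes, 9010 had several probe sets. Of the 8959 genes called, 409 had another probe set called in the opposite direction.

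The knockout and wild-type arrays were compared with lmFit and eBayes of limma 3.58.1 (R 4.3.3), two-sided, with no covariate and no filter on dim genes. P-values were adjusted by Benjamini-Hochberg over the 18193 genes, with a threshold of 0.05. A fold change is 2 to the power of the difference of mean log2 values, with a moderated standard error (SE). Lists of genes were tested with limma's camera (inter-gene correlation preset to 0.01), adjusted over 22 lists. For each list the number of called members is given over all genes and adjusted over the list alone. Camera was repeated with an estimated correlation, and fry was run beside it. In text, "adjusted p" of a gene is limma's and that of a list is camera's.

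The lists, the rule for named genes, the tests of the genes and the lists, and most alternatives were fixed before the data were examined. The rule named Fh1, then the 8 characterised genes with the largest change in each direction whose 3 knockout values lay all on one side of the 3 wild-type values. It then took from each list the 3 called members with the largest change and the largest in the other direction. Where fewer than 2 members passed, it took the 2 with the smallest p. Sex-linked genes were given as values only. Members measured only by probe sets that several genes share, such as Gapdh, were left out of the lists.

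On simulated data with the variance of these arrays, the fit for this comparison, run on 18193 genes, recovered 28% of genes changed by 0.5 on the log2 scale, 85% of those changed by 1 and 100% of those changed by 2. It made 10 false calls among 159. The simulation changed 50 genes by 0.5, 100 by 1 and 50 by 2, far fewer than the 8959 genes called in the data. Each gene had the same variance in both groups. Recovery in the data can therefore differ. With no simulated effect camera called 0 lists, and a shift of 0.5 in the NRF2 list was called. The simulated genes were independent of each other. The list check therefore says nothing about lists whose members vary together, as those estimated at 0.35 (tubular injury) and 0.52 (matrix) here.

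Alternatives were the mean of all probe sets of a gene, the genes at or above the median signal, a trended robust prior, re-centred or quantile-normalised arrays, array weights, a replicate block, each array left out, all probe sets, and stricter thresholds. Centring on the median of the tested genes and the tests of gene families were added after seeing the data. Tests between lists of markers used 100000 permutations of the genes, two-sided, and treat genes as independent. Python 3.11.15 and matplotlib 3.10.9 were used for tables and plots.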

Results

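Expression was measured in kidney epithelium of 3 Fh1 knockout samples and 3 wild-type littermate samples, each on 1 array. The design asks how knockout of Fh1 changes expression in cystic kidney tissue, against sex-matched disease-free littermates. Over 18193 genes, Pearson correlations across genes were 0.995 to 0.997 among knockout arrays, 0.988 to 0.992 among wild-type arrays and 0.952 to 0.964 between groups. Genes are not independent replicates in such a correlation. The median SD of a gene was 0.138 among wild-type arrays and 0.0857 among knockout arrays on the log2 scale. The first principal component held 80.4% of the variance and separated the groups, and the second held 8.63% and separated wild-type 2 from wild-type 3.

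Fh1 itself was lower in the knockout. Its 1 probe set read 12.32 ± 0.10 (SD, n = 3) in wild-type and 11.58 ± 0.04 (SD, n = 3) in knockout samples on the log2 scale, a 1.67-fold difference. The log2 fold change was -0.74 with SE 0.08 and adjusted p = 0.000396, and all 3 knockout values lay below all 3 wild-type values. Whether this probe set lies inside the deleted part of the gene is not known here. Of 19 other genes of the TCA cycle and the pyruvate dehydrogenase complex, 18 were also lower, with a list median of -0.65. Proximal tubule markers had a median of -1.34. The fall of Fh1 alone therefore cannot be told apart from this wider fall.

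Of 18193 genes, 3928 were higher and 5031 lower in the knockout, which is 49.2% of the genes tested. Changes of at least 2-fold ran the other way, with 990 genes higher and 617 lower. The median log2 fold change of all genes was -0.11. Lower genes made up 56.2% of the calls, 67.0% when each array was centred on the median of the tested genes, 52.8% with a replicate block and 44.2% among genes at or above the median signal. Groups did not overlap for 11435 genes, where chance gives 10%. Without knockout 1 there were 3117 genes higher in the knockout and 3160 genes lower in the knockout (50.3% lower), and without knockout 3 there were 3139 and 3279 (51.1% lower).

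The largest increase was in Sprr2f, a small proline-rich protein of squamous and stressed epithelia, at 297-fold (log2 fold change 8.21, SE 0.25). Its wild-type values of 5.36, 4.28 and 4.55 lay around the lower quartiles of those arrays (4.72 to 4.77), so the size of the fold is uncertain. Lcn2, the secreted iron-siderophore carrier used as a marker of kidney injury, was 62.8-fold higher, and Havcr1, the kidney injury molecule KIM-1, 26.9-fold higher. Immunoglobulin genes rose with them: Igk 36.5-fold, Iglv1 25.2-fold and another kappa variable gene 19.4-fold. Their probe sets may cross-react within the immunoglobulin family, so the individual gene is uncertain. Rbp4, the plasma retinol carrier, was 31.4-fold higher and Serpina10, a protease inhibitor of the coagulation system, had a log2 fold change of 4.17 with SE 0.11. Adjusted p-values of these 8 genes ran from 4.46e-06 to 0.000572. Wild-type 1 held the highest wild-type values of Lcn2 and the immunoglobulins, and without it the log2 fold changes were 6.57 for Lcn2, 5.92 for Igk, 5.30 for Iglv1 and 4.94 for the kappa variable gene.

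The largest decrease was in Cyp2d12, a cytochrome P450, which was 32.8-fold lower (log2 fold change -5.04, SE 0.35). Cyp2d12 and Sprr2f have close paralogs, so cross-hybridisation leaves the individual gene uncertain. Cyp2c23, an arachidonic acid epoxygenase of kidney, was 14.4-fold lower. Among transporters, the urea transporter Slc14a2 was 13.2-fold lower and the organic anion transporters Slc22a7 and Slco1a1 had log2 fold changes of -3.71 and -3.70. Bhmt, which remethylates homocysteine, was 14.7-fold lower, Hpd, of tyrosine breakdown, 12.9-fold lower, and Pvalb, the calcium-binding protein of the distal convoluted tubule, 12.5-fold lower. Adjusted p-values ran from 4.46e-06 to 0.00611. Bhmt, Slc22a7 and Slco1a1 had wide wild-type SDs of 1.54, 1.38 and 1.57, set by wild-type 2. Without it their log2 fold changes were -3.02, -2.92 and -4.60. Bhmt read -4.51 without wild-type 1 and -4.53 without knockout 1.

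**Figure D1:**
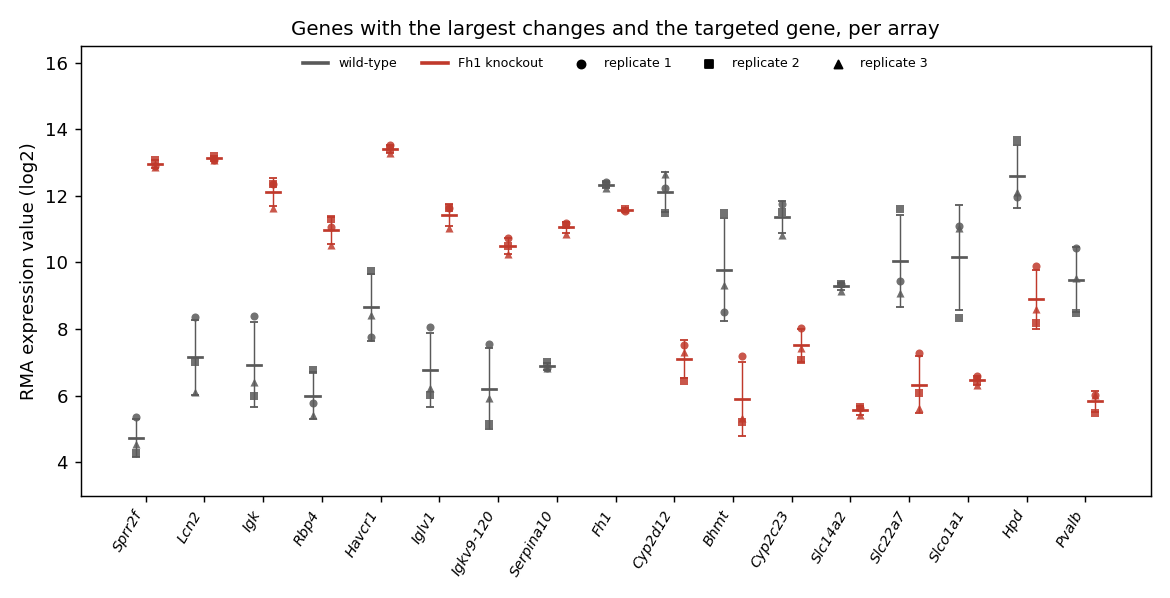
RMA expression values (log2 scale, y axis) of the 8 most increased genes, Fh1 and the 8 most decreased genes (x axis), per array. Symbols are replicates, bars the group mean and whiskers 1 SD (n = 3); the groups do not overlap for any gene shown, and wild-type 2 stands apart for Bhmt, Slc22a7 and Slco1a1.

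Among targets of the hypoxia-inducible factors (HIF), more rose than fell. Of 27 measured members, 16 were higher and 6 lower (17 and 7 adjusted over the list alone), and 5 did not pass. Without knockout 1 the lower members numbered 3, and without knockout 2 also 3. Ankrd37, an ankyrin-repeat HIF target, rose 7.53-fold, Ddit4, an inhibitor of mTORC1, 4.51-fold and Egln3, a HIF prolyl hydroxylase, 3.03-fold. Slc2a1, the glucose transporter GLUT1, rose 2.97-fold. Car9 and Car12, carbonic anhydrases, were 2.18-fold and 2.14-fold lower, and Vegfa did not pass (log2 fold change -0.14, SE 0.10, adjusted p = 0.259). Slc2a1, Car12 and Vegfa were chosen after their values were seen. The list median was 0.80 and camera gave adjusted p = 0.000152, against adjusted p = 0.121 with an estimated correlation. Within the brighter genes alone the list gave adjusted p = 0.0736. Beside this list, immune and matrix markers had medians of 1.48 and 1.36 and proximal tubule markers one of -1.34.

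Glycolytic genes rose and gluconeogenic genes fell. Of 12 glycolytic members, 10 were higher and 1 lower (11 and 1 adjusted over the list alone). Gapdh, left out of the list for its shared probe sets, had log2 fold changes of -0.05, -0.09 and -0.36 in them. None was called (limma adjusted p = 0.0656 to 0.644 over all probe sets). Hk2, hexokinase 2, rose 16.3-fold, Pfkp, platelet-type phosphofructokinase, 5.79-fold and Pfkl, liver-type phosphofructokinase, 2.63-fold, whereas the muscle-type Pfkm fell 1.58-fold. All 9 measured gluconeogenic members were lower (9 adjusted over the list alone). G6pc, glucose-6-phosphatase, fell 4.97-fold, Pcx, pyruvate carboxylase, 3.21-fold and Slc37a4, the glucose-6-phosphate transporter, 2.77-fold. Glycolysis had adjusted p = 1.21e-05 and gluconeogenesis adjusted p = 2.62e-05 by camera, and both had adjusted p = 0.121 with an estimated correlation. Markers of the proximal tubule, the nephron segment that makes glucose, had a median log2 fold change of -1.34.

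Transcripts of mitochondrial metabolism genes were lower. The TCA cycle list leaves out Fh1 and includes Pdha1, Pdhb and Dlat of the pyruvate dehydrogenase complex, which feeds the cycle. Of its 19 measured genes, 18 fell (18 adjusted over the list alone). Ogdh of the oxoglutarate dehydrogenase complex was 2.39-fold, mitochondrial isocitrate dehydrogenase Idh2 1.98-fold and Suclg2, a succinyl-CoA ligase subunit, 1.94-fold lower. Of 28 respiratory chain genes, 24 fell (25 adjusted over the list alone) and none rose. Ndufs1 fell 1.89-fold, Ndufa4 1.85-fold and Ndufs3 1.71-fold. Of 22 fatty acid oxidation genes, 21 fell (21 adjusted over the list alone), among them the thiolase Acaa2 at 2.46-fold, the nuclear receptor Ppara at 2.38-fold and medium-chain acyl-CoA dehydrogenase Acadm at 2.29-fold. The list medians were -0.65, -0.50 and -0.84. By camera the lists had adjusted p = 3.46e-07, 1.03e-07 and 6.61e-08, and with an estimated correlation adjusted p = 0.121, 0.133 and 0.121. Proximal tubule markers, which mark a cell type rich in mitochondria, fell in the same samples (median -1.34).

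Targets of NRF2, the transcription factor of the electrophile and oxidant response, rose. Of 26 members, 18 were higher and 1 lower (18 and 1 adjusted over the list alone), and without wild-type 2 18 were higher and 4 lower. Prdx1, Ftl1 and Esd were left out of the list for their shared probe sets. In these, log2 fold changes were 0.04 to 0.14 for Prdx1 and -0.04 to 0.10 for Ftl1, none called. Those of Esd were 0.05, 0.16 and 1.76, and only the last was called. Akr1b8, an aldo-keto reductase, rose 15.5-fold, Ephx1, microsomal epoxide hydrolase, 5.90-fold and Cbr3, a carbonyl reductase, 4.84-fold. Osgin1 fell 2.12-fold. Nqo1, the quinone reductase often used as the marker of this response, was 2.08-fold higher; it was chosen after its values were seen. The median was 0.72 and camera gave adjusted p = 4.10e-06, against adjusted p = 0.121 with an estimated correlation. Cbr3 read 9.48 in wild-type 2 against 7.45 in the other wild-type arrays, and its log2 fold change without wild-type 2 was 2.95 against 2.27. Immune and matrix markers had medians of 1.48 and 1.36 in these samples, and proximal tubule markers one of -1.34.

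Genes of the ATF4 amino acid stress response rose as well, with 12 of 18 members higher and 2 lower (12 and 2 adjusted over the list alone). Aldh18a1, of proline synthesis, rose 8.30-fold, asparagine synthetase Asns 5.41-fold, and the cationic amino acid transporter Slc7a1 rose with a log2 fold change of 2.32. The mitochondrial serine hydroxymethyltransferase Shmt2 fell 2.46-fold. Camera gave adjusted p = 4.38e-05 and, with an estimated correlation, adjusted p = 0.121. The medians of immune, matrix and proximal tubule markers in the same samples were 1.48, 1.36 and -1.34. Among 15 genes of arginine metabolism and the urea cycle, 2 rose and 8 fell (2 and 8 adjusted over the list alone), and the list as a whole did not pass (adjusted p = 0.0612). Gatm, of creatine synthesis, fell 5.74-fold and Asl, argininosuccinate lyase, which releases fumarate, 2.35-fold. Arginase 2, Arg2, was 3.85-fold higher (log2 fold change 1.95, adjusted p = 0.0414). Wild-type 2 read 10.67 for Arg2, inside the knockout range, and without it the log2 fold change was 2.83. Leaving out any 1 of the other 5 arrays ended the call of Arg2, with log2 fold changes of 1.38 to 2.08 and adjusted p of 0.0791 to 0.126, which left 1 member of the arginine list higher. With a trended robust prior the adjusted p of Arg2 was 0.103. Without wild-type 3 the arginine list passed (adjusted p = 0.0451).

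Of 11 haem metabolism genes, 7 fell and 1 rose (7 and 1 adjusted over the list alone), and the list did not pass (adjusted p = 0.0612). Hmox1, haem oxygenase 1, rose 2.87-fold. Alad and Uros, enzymes of haem synthesis, fell 2.10-fold and 1.86-fold. Without knockout 1 the lower haem genes numbered 4, and without knockout 3 also 4. Without wild-type 2 the haem list passed (adjusted p = 0.0360).

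Cell cycle genes were higher, with 21 of 27 members up and 1 down (22 and 1 adjusted over the list alone). Mki67, the proliferation antigen Ki-67, rose 3.75-fold and Top2a, topoisomerase II alpha, 3.26-fold; 1 of the 3 Top2a probe sets was called in the opposite direction. Cdkn1a, the cyclin-dependent kinase inhibitor p21, rose 4.90-fold. The mitotic transcription factor gene Foxm1 was 1.82-fold lower. The list had adjusted p = 4.47e-09 by camera, against adjusted p = 0.0520 with an estimated correlation. Immune cell markers had a median of 1.48 in these samples.

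Tubular injury and dedifferentiation genes had the highest list median, 2.29. Of 21 members 20 rose (21 adjusted over the list alone) and none fell. Besides Lcn2 and Havcr1, Cd44, a hyaluronan receptor of injured tubules, rose 16.6-fold. Camera gave adjusted p = 5.43e-14, and with an estimated correlation adjusted p = 0.121. Immune and matrix markers rose in the same samples (medians 1.48 and 1.36), and immune or stromal cells also express some members, such as Cd44. Of 16 polycystic and ciliary genes, 5 rose and 4 fell (5 and 4 adjusted over the list alone), and the list did not pass (adjusted p = 0.210). Ofd1 rose 2.23-fold, Bicc1 2.02-fold and Pkhd1, the fibrocystin gene, 1.70-fold. Bbs4 was 1.48-fold lower, a call that ended without knockout 1 (log2 fold change -0.53, adjusted p = 0.0625) and without knockout 3 (log2 fold change -0.54, adjusted p = 0.0586). Without knockout 3 the lower members of this list numbered 2.

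Markers of the proximal and distal nephron fell. Of 22 proximal tubule markers, 19 were lower (19 adjusted over the list alone) and none higher. The neutral amino acid transporter Slc6a19 fell 7.29-fold, the lactate transporter Slc5a12 6.68-fold and the glucose transporter SGLT2, Slc5a2, 5.29-fold. Aqp1 did not pass (log2 fold change -0.04, SE 0.12, adjusted p = 0.813) and was chosen after its value was seen. Of 12 loop of Henle and distal tubule markers 11 fell (12 adjusted over the list alone). Egf fell 12.2-fold and the thiazide-sensitive cotransporter Slc12a3 3.73-fold. These lists had adjusted p = 4.47e-09 and 1.01e-05 by camera, and for both adjusted p = 0.121 with an estimated correlation. Of 15 collecting duct markers, 7 fell and none rose (7 and 0 adjusted over the list alone; 1 rose without wild-type 1 and 1 without wild-type 2), and the list did not pass (adjusted p = 0.0664); it passed without wild-type 1 (adjusted p = 0.0483) and without knockout 3 (adjusted p = 0.0179). Slc26a4 and Slc4a1, anion exchangers of intercalated cells, fell 5.45-fold and 4.32-fold, and Aqp4, a water channel of principal cells, 4.28-fold. Immune and matrix markers moved the other way in the same samples, with medians of 1.48 and 1.36.

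**Figure D2:**
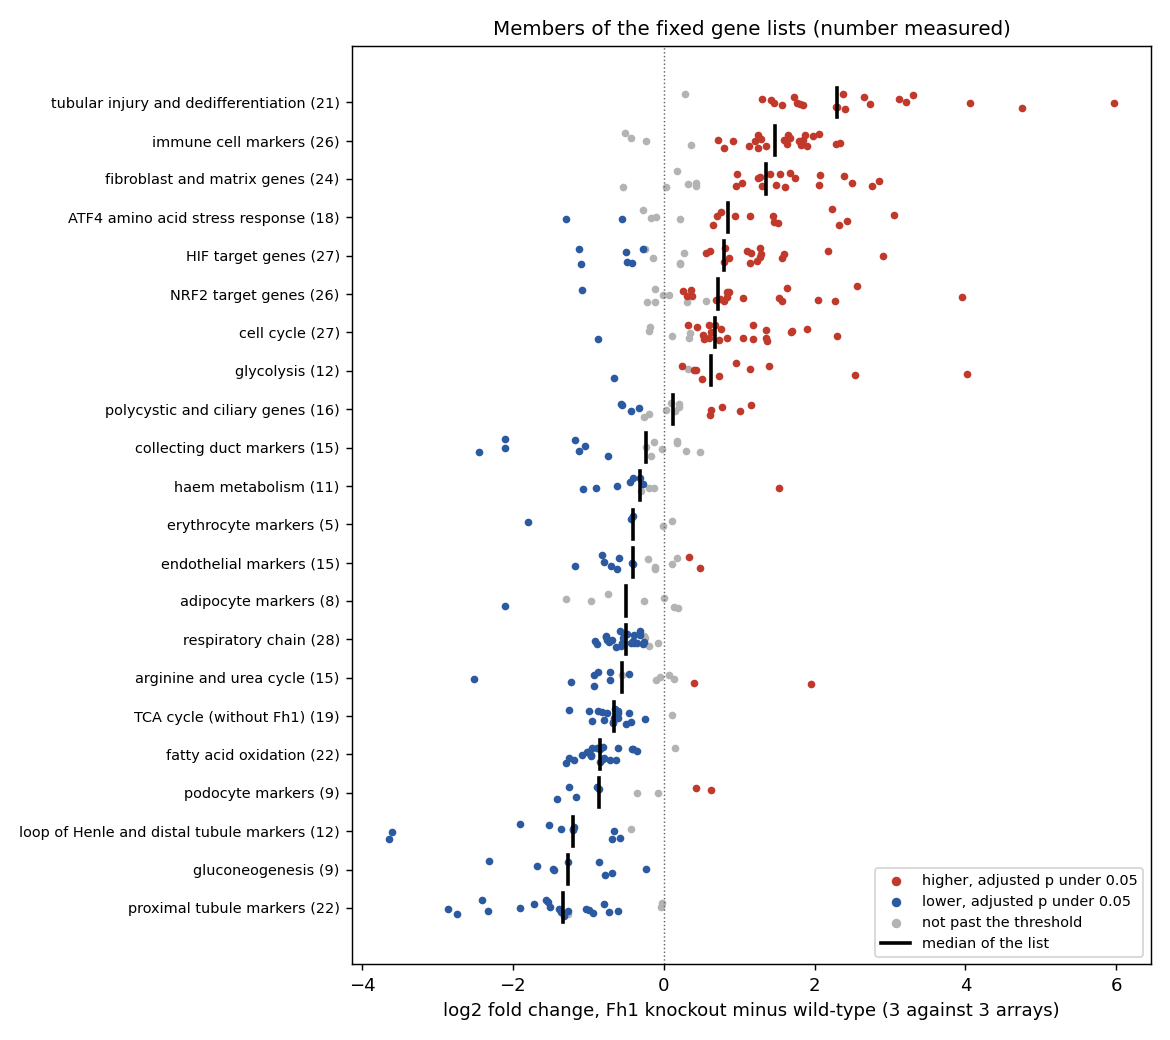
Log2 fold changes (knockout minus wild-type, x axis) of the members of 22 gene lists (y axis, with the number measured), each point 1 gene; colour gives the call at adjusted p under 0.05 and black bars the list median. The injury list has a median of 2.29 and the proximal tubule list one of -1.34.

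Immune cell markers rose, 22 of 26 (22 adjusted over the list alone), with none lower (1 lower without wild-type 3). Laptm5, a lysosomal protein of haematopoietic cells, rose 5.08-fold, and C1qb and C1qc, complement subunits made by macrophages, 4.86-fold and 4.16-fold. Camera gave adjusted p = 2.57e-10, against adjusted p = 0.121 with an estimated correlation. Of 24 fibroblast and matrix genes 18 rose (18 adjusted over the list alone) and none fell (1 without knockout 3). Fibronectin, Fn1, rose 7.25-fold, collagen III, Col3a1, 6.77-fold and the metalloproteinase inhibitor Timp1 5.65-fold. Camera gave adjusted p = 4.47e-09, against adjusted p = 0.172 with an estimated correlation.

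Lists of podocyte, endothelial, adipocyte and erythrocyte markers did not pass. Of 9 podocyte markers 5 fell and 2 rose (6 and 2 adjusted over the list alone; adjusted p = 0.0822). The slit diaphragm gene Nphs1 fell 2.24-fold, Clic5 2.39-fold and Cdkn1c 2.67-fold, and Kirrel rose 1.54-fold. Leaving out wild-type 2, wild-type 3, knockout 1 or knockout 2 left 1 podocyte marker higher. Of 15 endothelial markers 8 fell and 2 rose (8 and 2 adjusted over the list alone; adjusted p = 0.0942). Ehd3, of glomerular endothelium, fell 2.26-fold, Emcn 1.76-fold and the angiopoietin receptor Tek 1.73-fold, and Cd34 rose 1.40-fold. Emcn lost its call without knockout 1 (log2 fold change -0.69, adjusted p = 0.0675), and Cd34 without knockout 2 or 3 (log2 fold change 0.46 in both, adjusted p = 0.0623 and 0.0618). Without knockout 1 the lower endothelial markers numbered 5, and without knockout 2 or 3 the higher ones numbered 0 by limma. Of 8 adipocyte markers, Lpl alone passed, at 4.30-fold lower (1 adjusted over the list alone; adjusted p = 0.536); Lep had a log2 fold change of -0.97 with SE 0.51, and -0.27 without wild-type 2. The adipocyte list passed without knockout 3 (adjusted p = 0.0465), with 2 members lower. Of 5 erythrocyte markers 3 fell (3 adjusted over the list alone; adjusted p = 0.216), with Alas2, the erythroid enzyme of haem synthesis, 3.49-fold, Hba-a1 1.35-fold and Hbb-b2 1.32-fold lower. Hba-a1 and Hbb-b2 belong to near-identical globin families and read at most 4.42 and 5.53 on any array, so their values are uncertain. A probe set that several beta-globin genes share (Hbb-b1, Hbb-bs and Hbb-bt among them), left out of the list, fell further. Its log2 fold change was -1.87 with SE 0.10 (limma adjusted p = 2.34e-05 over all probe sets). Hba-a1 lost its call with quantile normalization (log2 fold change -0.32, adjusted p = 0.0608) and without knockout 2 or 3 (log2 fold changes of -0.43 and -0.40, adjusted p = 0.0557 and 0.0625). Hbb-b2 lost its call without knockout 1 or 2 (log2 fold changes of -0.34 and -0.40, adjusted p = 0.0796 and 0.0616), which left 1 erythrocyte marker lower without knockout 2.

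Sex-linked genes set 1 array apart. Wild-type 2 read 11.96 for Xist, the transcript that silences an X chromosome in female cells, where the other 5 arrays read 5.61 to 7.97. For the Y-linked genes Eif2s3y, Kdm5d and Uty it read 6.20, 4.38 and 5.86, below all other arrays. The knockout arrays read 9.54 to 9.59 for Eif2s3y, and knockout 1 read 7.97 for Xist. The 3' minus 5' signal of the beta-actin control, a measure of RNA integrity, was 0.90 ± 0.07 (SD, n = 3) in wild-type and 0.70 ± 0.03 (SD, n = 3) in knockout arrays on the log2 scale. For Gapdh it was -0.15 ± 0.01 and -0.11 ± 0.03 (SD, n = 3).

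**Figure D3:**
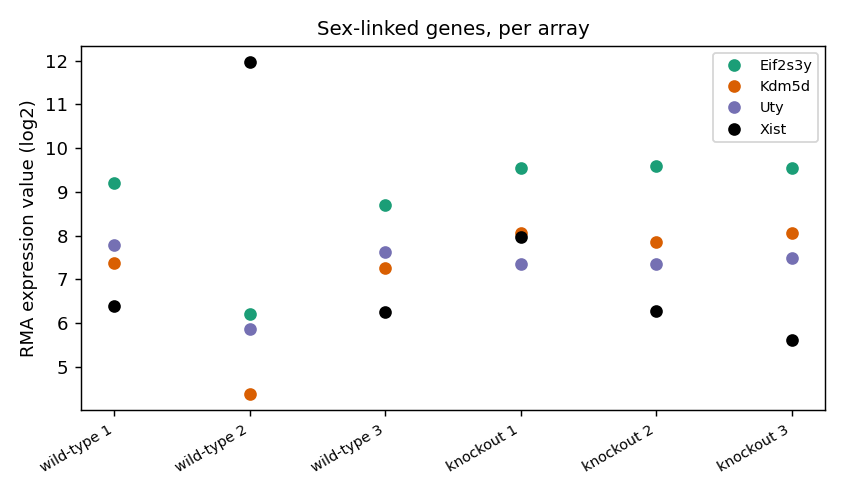
RMA expression values (log2 scale, y axis) of Xist and 3 Y-linked genes on each of the 6 arrays (x axis), each point 1 array. Wild-type 2 reads 11.96 for Xist and lies below all other arrays for Eif2s3y, Kdm5d and Uty.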

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

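The tests in this part were chosen after the results were seen, except the splits of the arrays. Probe sets outside the tested genes changed in both directions. Of 9160 with no gene listed, limma called 1802 higher and 1721 lower (38.5%, against 45.2% of the probe sets with 1 gene), and 1775 were called higher with no overlap between groups. Of 932 that several genes share, 282 were higher and 179 lower, and 279 were higher with no overlap. The beta-actin control probe sets were higher in the knockout by 0.377 (3' part), 0.576 (5' part) and 0.557 (middle part) on the log2 scale. Among other mouse control transcripts, the 18S ribosomal RNA probe sets (0.12, 0.48 and 0.36, with SE 0.31, 0.44 and 0.36) and those of Gapdh (-0.01 to -0.05) did not pass, those of pyruvate carboxylase fell (-1.46 to -1.77) and those of the transferrin receptor fell (-0.73 to -0.80).

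Wild-type 2 differed from wild-type 1 and 3 in sex-linked genes, although the design names sex-matched littermates. Over 10 kidney genes known to be higher in male mice its median difference from the other 2 wild-type arrays was -1.70 on the log2 scale, with 10 of 10 below 0, and over 3 genes known to be higher in females it was 2.48. A female animal among the wild-type samples is a candidate explanation, and all 3 knockout arrays carried Y-linked signal. An array that deviates over all genes is argued against by its median absolute difference, which was 0.829 times that of the most deviant other wild-type array. Without it 8670 genes were called, of which 7904 were shared with the 8959 of all arrays.

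Nephron markers fell while immune and matrix markers rose. Dilution of kidney cells by incoming cells would lower all segments alike, but the proximal tubule median minus that of 8 principal cell markers was -1.415 (permutation p = 0.00037, Benjamini-Hochberg adjusted 0.000493 over 4 comparisons). Medians of the loop of Henle and distal tubule (-1.20) and of 7 intercalated cell markers (-1.13) lay near the proximal tubule one. The contrast therefore rests on the principal cell markers, a part of the collecting duct list. A lower share of tubule cells would raise all other cell types alike, but the immune median lay 1.88 above the endothelial one (permutation p = 3e-05, adjusted 6e-05). Neither comparison excludes dilution as a part of the change. Both permutations treat genes as independent, so their p-values may be too small. The estimated correlation was 0.49 for the collecting duct list, 0.24 for endothelial and 0.18 for immune and proximal tubule markers. Lower expression per cell and a loss of single segments cannot be told apart in bulk tissue, where the proximal tubule median was -1.34.

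More genes were lower than higher (56.2% of calls), but the lower share was 50.3% without knockout 1 and 51.1% without knockout 3. Centring each array on the median of the tested genes gave 67.01%, which decides nothing about the scaling, since the knockout arrays had the higher medians and centring lowered every gene in them. The share followed signal: 83.3% of calls were lower among the 6065 dimmest genes, 49.6% among the 6064 genes of middle signal and 44.9% among the 6064 brightest. Quantile normalization narrowed this trend to 70.3%, 62.6% and 51.3% but left 59.21% of all calls lower (55.6% to 58.5% with 1 array left out). It also moved the median log2 fold change of the genes of middle signal from -0.04 to -0.14. The remaining share therefore decides nothing about the part of the trend that the normalization removed. The scaling, the trend with signal and a change of expression in the knockout stay open.

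The 6 arrays can be split into groups of 3 in 10 ways, too few for a share under 0.05. By limma the real grouping called 8959 genes, and 1 of the 10 splits, the real one, gave as many; the highest other split called 0, with at most 191 genes at an unadjusted p under 0.05. For gene lists the real grouping called 14 by camera, 4 of the 10 splits gave as many, and the highest other split called 16. Each other split sets 2 arrays of one group and 1 of the other against the rest, and so holds part of the knockout difference. Mixing the groups also widens the spread within each side for genes that differ, which lowers the number of genes called. The count of 0 genes therefore decides nothing about chance.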

How the results depend on the processing

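Of 86 named genes besides Fh1, none reversed under 14 alternatives (75 of them under the fit on brighter genes, which leaves out 11), and 6 lost their call under some (Arg2, Bbs4, Emcn, Cd34, Hba-a1, Hbb-b2). Fh1 kept its call under 14 alternatives, from -0.82 to -0.70. Some named genes had probe sets that moved the other way. Those in the stated direction were 3 of 5 for Laptm5, 1 of 2 for Kirrel and 2 of 3 for Slc7a1 and Top2a. For Cd44 and Foxm1 they were 3 of 4. Of these genes, only Top2a had a probe set called in the opposite direction. Over all probe sets except controls, 9271 probe sets were higher and 10529 lower. Higher genes numbered 990 at 2-fold or more. Lower genes numbered 617 at 2-fold or more, 2371 at adjusted p under 0.01, 2334 among genes at or above the median signal, and 3160 to 4810 with 1 array left out. Centring on the tested genes was chosen after seeing the data. With an estimated correlation 0 of 22 lists passed camera (8 at an unadjusted p under 0.05). That correlation was -0.003 for HIF targets and -0.007 for the cell cycle, below the preset 0.01. Members that vary together therefore do not account for the weaker result of either list. Adjusted p was 0.0520 for the cell cycle, 0.133 for the respiratory chain and 0.172 for matrix genes. It was 0.121 for the other 11 lists called at the preset correlation. Under 16 other alternatives these 14 lists kept their call in 223 of 224 results; HIF targets gave 0.0736 among the brighter genes, those at or above the median signal. Lists not called gained a call as follows, all downward but the polycystic list. Among the brighter genes, adjusted p was 0.0119 (arginine), 0.0162 (haem), 0.0169 (collecting duct), 0.0285 (podocyte) and 0.0106 (endothelial). With quantile normalization it was 0.0297 (haem and collecting duct), 0.0413 (podocyte) and 0.0245 (endothelial), and with array weights 0.0490 (arginine and collecting duct) and 0.0494 (haem). With brighter members only it was 0.0340 (arginine and endothelial). With fry, which does not compare a list with other genes, it was 0.000124 (arginine), 0.000275 (haem), 0.00481 (polycystic), 0.0120 (collecting duct), 0.000512 (podocyte), 0.00713 (endothelial) and 0.000666 (erythrocyte). With 1 array left out it ran from 0.0451 to 0.0910 (arginine), 0.0360 to 0.0729 (haem), 0.0179 to 0.142 (collecting duct) and 0.0465 to 0.891 (adipocyte). The cause was not tested. Same-numbered samples did not deviate together from their group means (r = -0.10, -0.13 and -0.13), and no sample correlated best with its own number. With 3 samples per group this cannot exclude that the numbers pair them. A replicate block called 7440 genes against 8959 and gave the arginine list 0.0409, with no other list changing. No array decided a list called at the preset correlation. With 3 arrays per group and no detection call, small changes of dim genes are the least certain.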

Other observations

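All tests and genes in this part were chosen after the data were seen. Genes that share a symbol stem were grouped into 545 families of at least 5 and tested with camera. With the preset correlation 20 families passed, and with an estimated one none did (lowest adjusted p = 0.747, 15 families at an unadjusted p under 0.05). Ribosomal protein genes were higher, with 19 of 24 Rpl genes and 18 of 22 Rps genes called up (medians 0.48 and 0.48; adjusted p = 6.96e-06 and 6.47e-05, and for both adjusted p = 0.747 with an estimated correlation). The host genes of small nucleolar RNAs, Snhg, rose in 12 of 14 cases (median 0.62; adjusted p = 0.000413), as did 23 of 40 translation initiation factor genes, Eif (median 0.32; adjusted p = 0.000413), and both had adjusted p = 0.747 with an estimated correlation. In contrast, 30 of 47 mitochondrial ribosomal protein genes, Mrpl, fell (median -0.28; adjusted p = 0.0463, adjusted p = 0.754 with an estimated correlation, and 0.0883 without wild-type 2). In the same samples immune, matrix and proximal tubule markers had medians of 1.48, 1.36 and -1.34.

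Among other families, 8 of 11 annexin genes, Anxa, were higher (median 0.94; adjusted p = 0.0125), as were 7 of 13 interferon-inducible Ifi genes (median 0.71; adjusted p = 0.0286). Both had adjusted p = 0.747 with an estimated correlation, and immune cell markers had a median of 1.48 in the same samples. Inward-rectifier potassium channels, Kcnj, fell in 10 of 15 cases (median -0.43; adjusted p = 0.0353, and adjusted p = 0.747 with an estimated correlation). Of 344 solute carrier genes, 173 fell and 50 rose (adjusted p = 0.00360, and adjusted p = 0.747 with an estimated correlation). Beside these families, proximal tubule markers had a median of -1.34. Single genes known from B and plasma cells, for which no list was tested, were higher: Pou2af1 13.1-fold (adjusted p = 3.26e-05), the joining chain Jchain 9.12-fold (adjusted p = 0.00108) and the heavy chain Ighm with a log2 fold change of 3.58 (adjusted p = 0.000376), although 1 of the 11 probe sets of Ighm was called in the opposite direction. The B cell genes of the immune list were also higher, Cd79a 1.88-fold, Cd79b 3.03-fold and Ms4a1 3.52-fold.

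Within the collecting duct, 7 intercalated cell markers had a median log2 fold change of -1.13 and 8 principal cell markers one of 0.07 (permutation p = 0.0195, Benjamini-Hochberg adjusted 0.0195 over 4 comparisons). This p treats genes as independent and may be too small, since the estimated correlation of the collecting duct list was 0.49. Aqp2, the vasopressin-regulated water channel, read -0.23 with SE 0.13, and the sodium channel subunit Scnn1b 0.18 with SE 0.11. Aqp4, also a principal cell gene, fell.

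Against the 2 wild-type arrays without the Xist signal, male-biased kidney genes were lower in the knockout, with a median of -1.93 over 10 genes, and Slco1a1 read -4.60. Without wild-type 2, calls were gained by Cyp2j13 (-1.49), Slc7a13 (-1.99) and Cyp7b1 (-1.94), and by the female-biased Slc7a12 (1.75) and Cyp4a14 (2.89), with adjusted p from 3.25e-05 to 0.00279, whereas the female-biased Hao2 was lower (-1.20). With all 6 arrays the male-biased median was -1.31. Proximal tubule markers fell in the same samples (median -1.34, 19 of 22 lower), and 4 of the 10 male-biased genes (Kap, Cyp2e1, Cyp4b1 and Slc7a13) are among them.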
